A study of Komagataella pastoris with 4 samples.

How the data were processed

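Total RNA of the yeast Komagataella (Pichia) pastoris, strains GS115 and ΔROP, grown in YNB methanol for 6 h or 24 h, was measured on 4 custom Agilent arrays, with 1 array for each of 4 groups. Per the labels, RNA was isolated by the hot-phenol method, primed with oligo-dT, amplified and labelled with Cy3 by the Quick-Amp kit. The deposited scanner files hold intensity values per spot that the authors extracted with Agilent Feature Extraction 10.5, which subtracted the background and removed spatial trends within each array, without normalization between arrays. The deposited files also hold other columns, the flags and control types of each spot, which were used as filters. The deposited value table holds log2 values per probe, already scaled so that the 75th percentile of each array is near 0. All 4 arrays were on 1 slide and in 1 scan.

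Control spots and spots flagged as non-uniform or as population outliers were left out. The processed signal was taken to log2 and the array's 75th percentile over gene spots was subtracted. Replicate spots of a probe were averaged (4910 probes had 3 spots and 239 had 2), and a gene took the median over its probes. Of 5023 single genes 4973 had 1 probe. Another 10 units stand for sets of genes that share probes, and 10 custom probes were kept out of gene counts and lists. A gene counted as measured in a comparison when it was well above background on every array compared. Where it was so on 1 array only, a lower bound of the fold against the other array's lowest well-above-background level is given as "at least". A probe saturated on its brighter side also gives a lower bound, and genes saturated on both sides give none. Gene names, descriptions and chromosome positions come from the probe annotation in the deposited files, whose genome build is not given in the sources used here. The reference gene table used here matched 0 of the locus tags, so its names were not used.

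The comparisons were ΔROP against GS115 at 6 h and at 24 h, 24 h against 6 h in each strain, and the difference of the genotype differences. With 1 array per group they have no test, and genes of at least 2-fold were counted. The technical standard error came from the spots, with a median of 0.02 in each pairwise comparison. The additive model of genotype and time was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. It had 1 residual and 6.44 prior degrees of freedom. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

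Before the data were examined, 26 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Lists were matched by product description, and 66 matches whose description names another protein were removed from the text alone. A list's median is set against 10000 random lists of the same size matched on mean level in 20 bins, and a list counts as outside when it falls outside their middle 95%. Lists with fewer than 3 measured genes have no percentile. This describes these arrays and is not a test across cultures. Named genes are all measured members of the methanol, gluconeogenesis and glyoxylate lists, the 8 largest rises and 8 largest falls with a described product in each genotype comparison, 6 per direction in each time comparison, 5 per direction in the difference of differences, the 10 smallest p of the model, the 3 largest bounds per direction and up to 4 members of each list described. Bounds under 2-fold and some genes under this rule are not printed.

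The alternatives were quantile normalization, median centring, cyclic loess, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes, saturated probes left out, the brightest probe or the mean over probes of a gene, a 3-fold threshold and, for the model, a variance trend. After the data were seen, quantile normalization and cyclic loess were each combined with leaving out saturated probes for the time comparisons.

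The steps were tested on simulated data with genes of middle brightness changed 3-fold or 6-fold, in which unchanged genes gave 2 calls in the difference of differences and 0 in every other comparison. The simulated noise between arrays was a fixed, chosen value, since no group had a replicate to estimate it from. These calls therefore give no rate of false calls for the real comparisons, and the recovery below holds for that noise. The 2-fold count recovered 100% of both sizes at 6 h (4972 genes run). At 24 h it recovered 98.7% of the 3-fold and 100% of the 6-fold changes (4931 genes run). In the time comparisons it recovered 100% of both sizes, in 4970 genes for GS115 and 4931 for ΔROP. For the difference of differences it recovered 96.0% of the 3-fold and 100% of the 6-fold changes (4931 genes run), and the additive model recovered 100% of both sizes (4931 genes run). In the simulated comparison at 6 h 5.5% of 200 unaffected lists lay outside the middle 95%. These lists were random genes with independent noise, so the share does not hold for lists whose genes move together. No array was left out.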

Results

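Messenger RNA levels were measured in the methylotrophic yeast Komagataella (Pichia) pastoris with custom Agilent one-colour expression arrays. The parent strain GS115 and the strain ΔROP were grown in minimal medium with methanol (YNB methanol) for 6 h or 24 h. Each of the 4 groups held 1 array, so no value below has a replicate error, and the number of arrays limits the precision of every comparison. Outside the additive model, a standard error given below is technical, from the replicate spots of a probe on the same arrays, and does not include differences between cultures. By its title the series asks how a zinc finger protein represses the enzyme phosphoenolpyruvate carboxykinase in cells short of biotin and pyruvate carboxylase.

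The arrays carried 5149 gene probes for 5043 measured units, 5023 of them single genes. On the GS115 array at 6 h 98.6% of the gene spots were well above background, on the ΔROP array at 6 h 99.2%, on the GS115 array at 24 h 98.9% and on the ΔROP array at 24 h 97.4%. The brightest probes reached the ceiling of the scanner. Saturated spots made up 5.75% of the gene spots for GS115 at 6 h, 4.61% for ΔROP at 6 h, 2.63% for GS115 at 24 h and 3.12% for ΔROP at 24 h. The 75th percentile of the signal was 15449, 12044, 6936 and 8016 in the same order. Levels are log2 signals relative to that percentile of the same array. A gene saturated on both arrays of a comparison gives no fold, because its difference only repeats the difference in array brightness.

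The transcript of PAS_chr3_0554 was lost in ΔROP. The files describe this gene, on chromosome 3 from 1056655 to 1059447 on the minus strand, as a zinc-finger protein involved in transcriptional control of both nuclear and mitochondrial genes. Its level was 0.76 in GS115 at 6 h and 1.54 at 24 h, against -10.65 and -9.49 in ΔROP, where it was not above background. It was at least 960-fold lower in ΔROP at 6 h and at least 471-fold lower at 24 h. Custom probes for the same gene, Mxr2s and Mxr2As, were lower by at least 29.7-fold and 51.0-fold at 6 h and by at least 18.7-fold and 23.1-fold at 24 h. No table used here gives any gene the name ROP, so the match of this locus to the deletion in the strain's name was not made from the annotation. The next gene on the array's numbering, PAS_chr3_0553, had levels of 0.05 and 0.32 at 6 h in GS115 and ΔROP, and of 0.62 and 0.62 at 24 h.

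**Figure D1:**
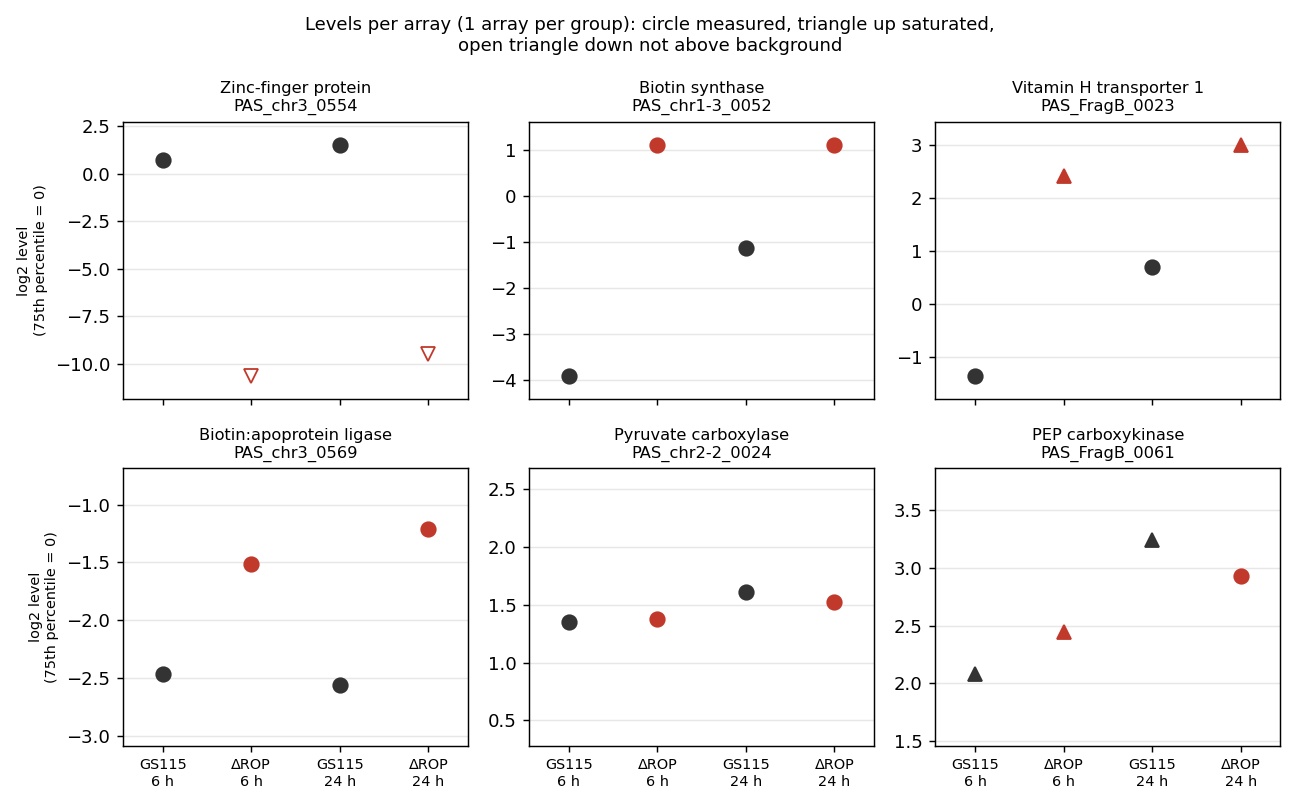
Log2 level (array 75th percentile = 0) of 6 genes on each of the 4 arrays, with GS115 in black and ΔROP in red and a separate vertical scale per gene. PAS_chr3_0554 is at 0.76 and 1.54 in GS115 and below background in ΔROP, and the 3 genes of biotin uptake, synthesis and attachment are higher in ΔROP at both times.

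The first comparison asked which transcripts differed between ΔROP and GS115 after 6 h on methanol. Biotin synthase, which makes biotin from dethiobiotin (PAS_chr1-3_0052, chromosome 1, 95232 to 96422), was 32.8-fold higher, a log2 difference of 5.04 with a technical standard error of 0.02. Vitamin H transporter 1, the biotin importer (PAS_FragB_0023, chromosome 1, 2705358 to 2706878), was at least 13.7-fold higher, since its probe was saturated in ΔROP. Biotin:apoprotein ligase, which attaches biotin to the carboxylases (PAS_chr3_0569), was higher by 0.95. In all, 15 of 4888 measured genes were at least 2-fold higher in ΔROP and 19 were at least 2-fold lower, without a test.

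Other genes far higher at 6 h included a plasma membrane aspartic protease (PAS_chr3_0299, 1.43), a mitochondrial S-adenosylmethionine transporter (PAS_chr3_0036, 1.41) and a sodium-phosphate cotransporter (PAS_chr2-1_0235, 1.40). A dienoyl-CoA isomerase (PAS_FragB_0022) was 2.30-fold higher and a phytanoyl-CoA dioxygenase domain protein (PAS_FragB_0025) 2.20-fold higher, and both genes lie near the vitamin H transporter gene on chromosome 1. The lowest described genes in ΔROP at 6 h included an activator of pseudohyphal growth (PAS_chr4_0326, -1.27), a nitrilase (PAS_chr2-1_0037, -1.25), a CCCH zinc finger protein (PAS_chr4_0329, -1.15) and a subunit of the CCAAT-binding Hap complex, a regulator of respiratory genes (PAS_chr4_0638, -1.15). A siderophore ferric reductase (PAS_chr4_0240, -1.09), a tRNA methyltransferase subunit (PAS_chr1-4_0374, -1.08), a cysteine transporter (PAS_chr1-3_0017, -1.05) and a ubiquitin ligase adaptor (PAS_chr2-2_0022, -1.04) followed. With normexp the CCAAT-binding subunit PAS_chr4_0638 and the methyltransferase subunit PAS_chr1-4_0374 were at -0.61 and -0.44, under 2-fold. The hypothetical gene PAS_chr3_0030, picked after its values were seen because of its size, was higher by 3.75 at 6 h and by 0.16 at 24 h. Among genes above background on 1 array only, the hypothetical gene PAS_chr1-3_0290 was at least 2.43-fold higher in ΔROP at 6 h.

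Iron uptake was the list with the lowest median in ΔROP at 6 h. Of its 10 measured genes 7 were below 0, with a median of -0.40 against -0.19 to 0.18 for the middle 95% of matched random lists. Beside the siderophore reductase stood a second ferric reductase (PAS_chr4_0399, -0.52), the iron oxidase (PAS_chr2-1_0787, -0.52) and the iron permease (PAS_chr1-4_0040, -0.52). Ergosterol synthesis was lower, with 13 of 18 genes below 0 and a median of -0.18 (random range -0.09 to 0.19). Examples were a C-8 sterol isomerase (PAS_chr4_0198, -0.70) and a lanosterol demethylase (PAS_chr1-3_0212, -0.43). Amino acid synthesis had 20 of 29 genes below 0 and a median of -0.10 (random range -0.09 to 0.13), inside with the mean over the probes of a gene, led by saccharopine dehydrogenase of lysine synthesis (PAS_chr1-1_0447, -0.71) and homoserine acetyltransferase of methionine synthesis (PAS_chr2-1_0383, -0.66). By 24 h iron uptake (-0.09), ergosterol synthesis (0.02) and amino acid synthesis (0.05) were inside their random ranges. Ribosome biogenesis was higher at 6 h, with 54 of 81 genes above 0 and a median of 0.13 (random range -0.09 to 0.05). A nucleolar protein (PAS_chr3_0903, 0.63) had the largest size in that list. Autophagy had 7 of 11 genes above 0 and a median of 0.20 (random range -0.18 to 0.17), with a kinase for vesicle formation (PAS_chr2-1_0641, 0.47) first.

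At 6 h the 3 genes of the biotin list, which holds genes whose description names biotin, had a median of 0.95, against -0.29 to 0.36 for random lists. Its other gene was acetyl-CoA carboxylase, a biotin enzyme of fatty acid synthesis (PAS_chr1-4_0249, 0.38). The levels of this gene, 2.02 in GS115 and 2.39 in ΔROP, were close to those of saturated genes. Genes saturated on both arrays had a median difference of 0.36, so its difference cannot be told apart from array brightness. The list was matched by description, so vitamin H transporter 1 was not a member. Of 26 lists 5 lay above and 3 below the middle 95%, where lists of genes that vary independently would put 1.3 outside. Genes of a pathway may move together between cultures, so more lists can lie outside without an effect of the genotype. Among the lists outside, the pentose phosphate list (median 0.35) owed its place to saturated probes, since its median without them was 0.07, inside the random range.

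Of the central genes for growth on methanol, few could be compared. The methanol list had a median of 0.36 at 6 h (random range 0.08 to 0.37) and -0.21 at 24 h (random range -0.29 to 0.27), both resting on saturated probes. The alcohol oxidase genes share their probes (PAS_chr4_0152 and PAS_chr4_0821), and these were saturated on all 4 arrays. Formate dehydrogenase (PAS_chr3_0932) was saturated on both arrays at each time, and so was the transketolase unit PAS_chr3_0832 and PAS_chr3_0834, whose probes are shared. Catalase A (PAS_chr2-2_0131) was saturated on both arrays at 6 h and not measured at 24 h. Formaldehyde dehydrogenase (PAS_chr2-1_0313) and dihydroxyacetone kinase (PAS_chr3_0841) had no usable spots in at least 1 array of each comparison. The remaining member, an esterase with S-formylglutathione hydrolase activity (PAS_chr3_0867), was higher in ΔROP by 0.24 at 6 h and by 0.25 at 24 h.

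Phosphoenolpyruvate carboxykinase, the gluconeogenic enzyme of the series title (PAS_FragB_0061, chromosome 1, 2775424 to 2777097), was saturated on both arrays at 6 h and gave no fold. At 24 h it was saturated in GS115 alone, and its ΔROP signal of 61239 was near the ceiling. Its log2 difference was -0.30, at least 1.24-fold lower in ΔROP under the main scaling only. It was -0.11 under quantile normalization and -0.20 under cyclic loess. Genes saturated on both arrays at 24 h had a median of -0.21, so a lower level in ΔROP is not established. Pyruvate carboxylase, which makes oxaloacetate from pyruvate (PAS_chr2-2_0024), differed by 0.02 at 6 h, negative under quantile normalization and cyclic loess, and by -0.08 at 24 h. Fructose-1,6-bisphosphatase (PAS_chr3_0868) was saturated on both arrays at 6 h and was not measured at 24 h. The list of gluconeogenesis, with these 3 genes, had a median of 0.34 at 6 h (random range 0.00 to 0.37), again from saturated probes, and too few genes at 24 h.

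The second comparison asked the same of the cells after 24 h. Vitamin H transporter 1 (PAS_FragB_0023) was at least 4.94-fold higher in ΔROP, again with a saturated probe there. Biotin synthase (PAS_chr1-3_0052) was 4.78-fold higher and biotin:apoprotein ligase (PAS_chr3_0569) was 2.55-fold higher. The biotin list had a median of 1.35 (random range -0.25 to 0.28), while acetyl-CoA carboxylase PAS_chr1-4_0249 was at -0.07, positive under quantile normalization and cyclic loess. Of 4859 measured genes 21 were at least 2-fold higher in ΔROP and 6 at least 2-fold lower, without a test.

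Also higher at 24 h were the phytanoyl-CoA dioxygenase domain protein (PAS_FragB_0025, 1.39), a multidrug transporter (PAS_chr1-4_0431, 1.39), the S-adenosylmethionine transporter (PAS_chr3_0036, 1.23), a permease proposed for carboxylic acids (PAS_chr1-1_0284, 1.22) and a pirin (PAS_chr1-4_0145, 1.12). The lowest described genes were arginase (PAS_chr2-2_0288, -1.42), malate synthase (PAS_chr4_0191, -1.26), a serine and threonine deaminase (PAS_chr2-2_0408, -1.12), proline permease (PAS_chr2-1_0659, -0.94) and a divalent metal transporter (PAS_chr3_0971, -0.85). A high-affinity zinc transporter (PAS_chr3_0516, -0.83), its neighbour encoding a putative anchored surface protein (PAS_chr3_0517, -0.81) and a histone acetyltransferase (PAS_chr3_1128, -0.79) came next. The list of nitrogen catabolism and permeases had a median of 0.01 (random range -0.12 to 0.09).

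Of the 35 proteasome genes 33 were higher in ΔROP at 24 h, with a median of 0.34 against -0.09 to 0.08 for random lists. Examples were the alpha 7 subunit of the core particle (PAS_chr3_0699, 0.65) and a regulatory subunit (PAS_chr1-3_0195, 0.46). Heat shock proteins and chaperones had 25 of 28 genes above 0 and a median of 0.25 (random range -0.11 to 0.07), led by an Hsp70 nucleotide exchange factor (PAS_chr2-1_0042, 0.98) and an activator of the Hsp90 ATPase (PAS_chr1-4_0072, 0.72). Both lists had been inside their random ranges at 6 h, with medians of 0.07 for the proteasome and 0.12 for heat shock proteins and chaperones. Folding in the endoplasmic reticulum was inside its range at 24 h (0.11, random range -0.17 to 0.16), and so was autophagy (0.01). Ribosome biogenesis had 69 of 80 genes above 0 and a median of 0.17 (random range -0.04 to 0.07), with PAS_chr3_0903 at 0.53. Mitochondrial ribosomal proteins had 41 of 52 genes above 0 and a median of 0.12 (random range -0.04 to 0.08). Translation factors and tRNA synthetases had a median of 0.07 (random range -0.07 to 0.06), which fell inside the range under quantile normalization and cyclic loess.

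In the same comparison fatty acid beta-oxidation had 11 of 13 genes below 0 and a median of -0.33 (random range -0.17 to 0.11), including a dienoyl-CoA reductase (PAS_chr3_0975, -0.52), a carnitine acetyltransferase (PAS_chr3_0761, -0.43) and the multifunctional enzyme (PAS_chr1-3_0016, -0.38). Peroxisome biogenesis had 10 of 11 genes below 0 and a median of -0.18 (random range -0.16 to 0.14), for example peroxin 20 (PAS_chr2-1_0458, -0.39). Both lists had been inside their random ranges at 6 h, with medians of 0.18 for beta-oxidation and 0.16 for peroxisome biogenesis. Sugar and polyol transporters had 8 of 9 genes below 0 at 24 h and a median of -0.25 (random range -0.21 to 0.15), a place lost with normexp background correction. The pentose phosphate list (-0.21) was inside when saturated probes were dropped, with a median of 0.01. Of 25 lists 6 lay above and 4 below the middle 95%.

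**Figure D2:**
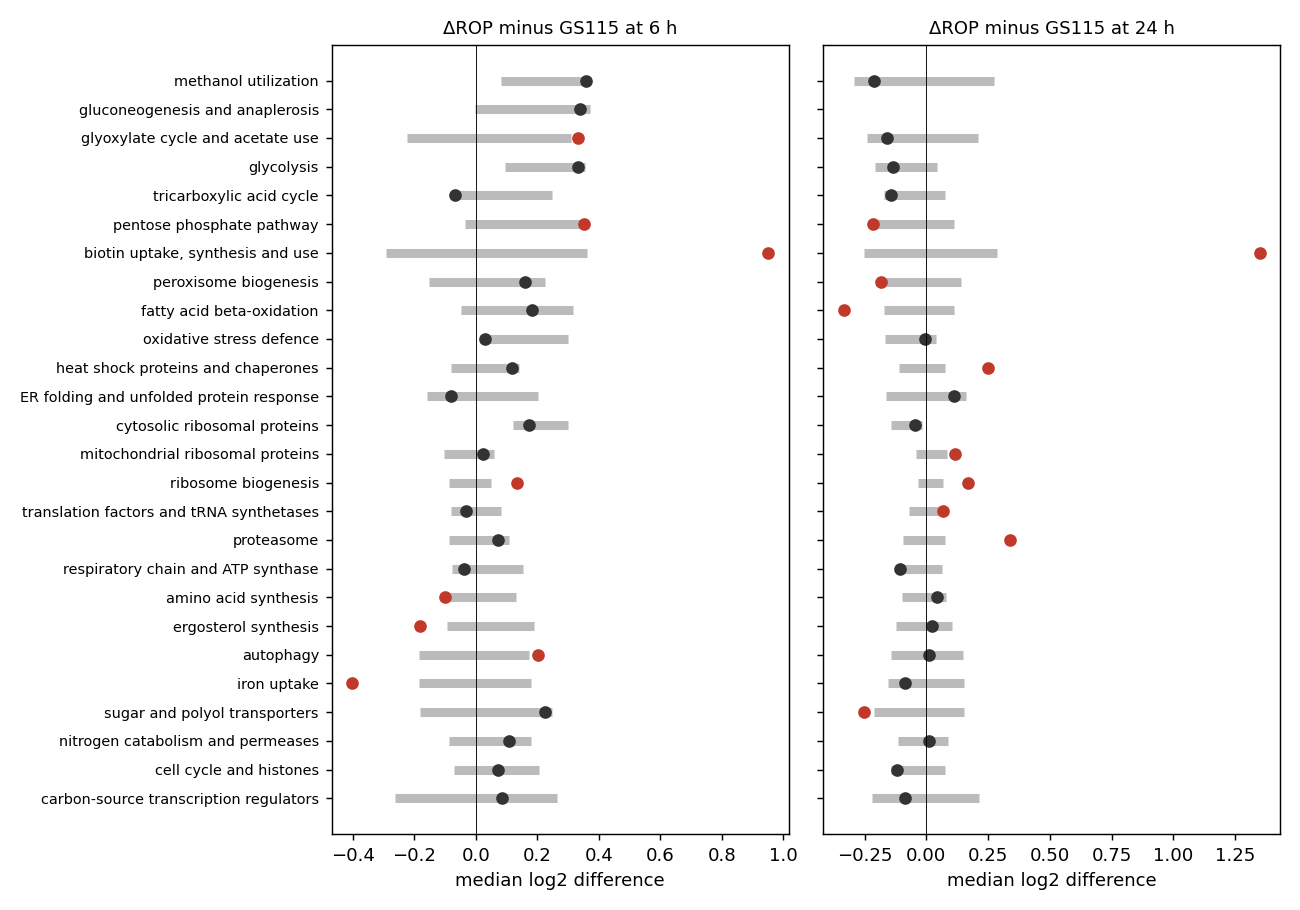
Median log2 difference between ΔROP and GS115 of each gene list at 6 h (left) and 24 h (right), as points, with the middle 95% of 10000 random lists matched on expression as grey bars. Red points lie outside their bar, with the biotin list at 0.95 and 1.35 and the proteasome list at 0.34 at 24 h.

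Of the 5 genes in the list of glyoxylate cycle and acetate use 4 were higher in ΔROP at 6 h, with a median of 0.33 against -0.22 to 0.31 for random lists. Isocitrate lyase (PAS_chr1-4_0338) was higher by 0.33, malate synthase PAS_chr4_0191 by 0.59 and its second gene PAS_chr1-4_0459 by 0.17, and the acetyl-CoA synthetase PAS_chr2-1_0767 by 0.55, while the synthetase PAS_chr3_0403 was at -0.28. At 24 h the median was -0.16, inside the random range of -0.24 to 0.21. Isocitrate lyase was at -0.73, the malate synthases at -1.26 and -0.05, and the acetyl-CoA synthetases at 0.08 and -0.16 in the same order. The difference between the times was not tested.

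Genotype differences at 6 h and at 24 h share no array. Among 4801 genes measured on all 4 arrays, 5 were at least 2-fold higher in ΔROP at both times, where independent lists would share 0.06. They were PAS_FragB_0023, PAS_FragB_0025, PAS_chr1-3_0052, PAS_chr3_0036 and the hypothetical gene PAS_chr2-1_0019. The hypothetical gene PAS_c131_0020 was at least 2-fold lower at both times, with levels of -1.58 in GS115 and -3.58 in ΔROP at 6 h and -2.14 and -3.28 at 24 h. Across genes, which are not independent replicates, the correlation of both differences was 0.12.

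**Figure D3:**
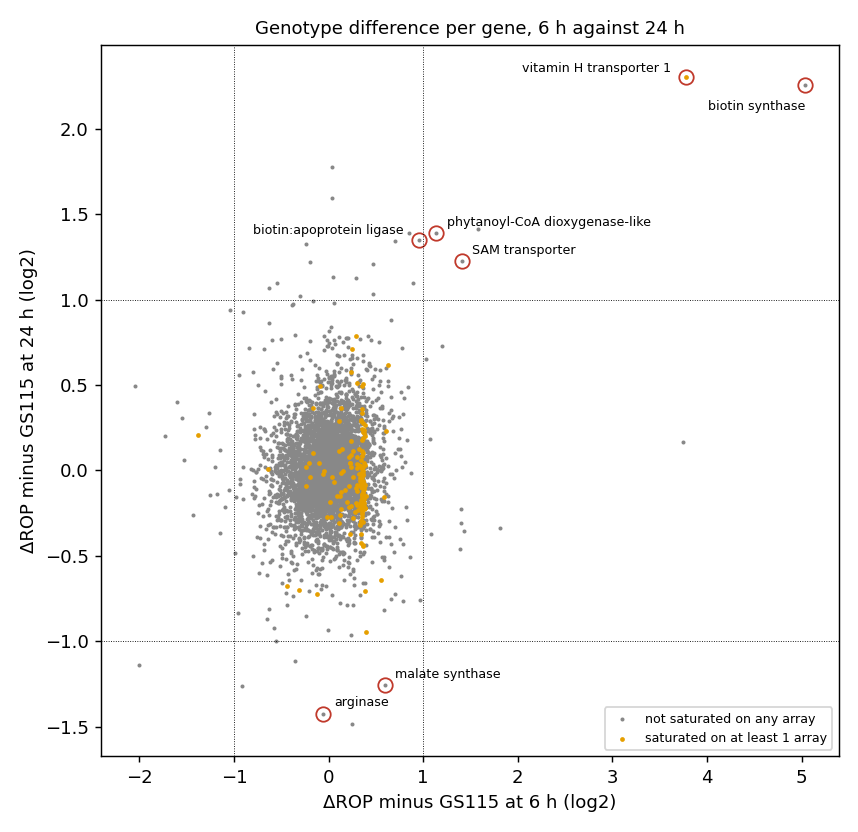
Log2 difference between ΔROP and GS115 of each gene at 6 h (horizontal) and at 24 h (vertical), with dotted lines at 2-fold and named genes circled. Biotin synthase (5.04 and 2.26) and vitamin H transporter 1 (at least 3.78 and 2.30) stand apart from the cloud, whose correlation is 0.12.

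An additive limma model of genotype and time was the only test that 4 arrays allow, with 1 residual degree of freedom. Whether the 6 h and 24 h samples of a strain came from separate cultures is not known here. If they did not, the error of the model leaves out differences between cultures. The model called 3 of 4801 genes higher in ΔROP at both times after Benjamini-Hochberg adjustment and 0 lower. Vitamin H transporter 1 (PAS_FragB_0023) had a log2 difference of 3.04 with a standard error of 0.30 and an adjusted p of 0.0346, with saturated ΔROP probes at both times, so that its size and error are uncertain. PAS_chr2-1_0019, higher by 1.58 at 6 h and 1.41 at 24 h, had an adjusted p of 0.0346, and the S-adenosylmethionine transporter PAS_chr3_0036 had 1.32 with an adjusted p of 0.0444, each higher at 2 of 2 times. At an unadjusted p under 0.05 there were 292 genes, where 240.1 are expected by chance. For time, the same model called 280 genes higher at 24 h and 545 lower, without correcting for the shift of the median over all genes given below, and this count was not recomputed under alternatives. Among the genes fitted, 58 were saturated on all 4 arrays, and their time differences only follow the array scaling. How many of the 280 they make up was not counted. The count of 3 went to 0 under quantile normalization, median centring, normexp, the deposited value table, no filter on dim probes and saturated probes left out, to 8 with a variance trend and to 15 with cyclic loess.

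Next in that ranking, without passing, were PAS_FragB_0025 (1.26, adjusted p 0.0529), PAS_c131_0020 (-1.57, 0.103), biotin:apoprotein ligase PAS_chr3_0569 (1.15, 0.103), PAS_chr3_0002 (-1.09, 0.105), biotin synthase PAS_chr1-3_0052 (3.65, 0.105), PAS_chr2-1_0018 (0.99, 0.105) and the multidrug transporter PAS_chr1-4_0431 (1.12, 0.122). The model counts the change of the biotin synthase difference between the times as error.

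The time comparisons asked what changed from 6 h to 24 h on methanol within each strain. In GS115 biotin synthase (PAS_chr1-3_0052) was 6.88-fold higher at 24 h. Other described genes among the highest included a serine and threonine deaminase (PAS_chr2-2_0408, 2.33), phenylpyruvate decarboxylase (PAS_chr3_0095, 2.27), an acetate transporter (PAS_chr1-1_0418, 2.14) and a hexose transporter (PAS_chr1-3_0004, 2.11). Lower at 24 h were a vacuolar membrane protein (PAS_chr4_0062, -1.56), a membrane protein (PAS_chr3_0930, -1.43), a sorting nexin (PAS_chr2-2_0030, -1.42), an RNA helicase (PAS_chr2-1_0030, -1.39) and the CCCH zinc finger protein (PAS_chr4_0329, -1.35). In all, 165 of 4892 genes were at least 2-fold higher and 113 at least 2-fold lower. Of those 165 genes, 91 were saturated on both arrays, so only their array scaling moved. Among the 4660 genes with no saturated probe 60 were higher and 112 lower.

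In ΔROP 42 of 4845 genes were at least 2-fold higher at 24 h and 56 at least 2-fold lower. Transporters were the highest described genes, with the multidrug transporter (PAS_chr1-4_0431, 2.53), a low-affinity iron transporter (PAS_chr2-2_0009, 2.08) and a methionine permease (PAS_chr3_0018, 2.04 with a technical standard error of 1.30). A protein kinase (PAS_chr1-3_0041, 1.97), phenylpyruvate decarboxylase (PAS_chr3_0095, 1.67) and the deaminase (PAS_chr2-2_0408, 1.57) followed. Lower were a DnaJ homolog (PAS_chr1-3_0174, -1.57), the vacuolar membrane protein (PAS_chr4_0062, -1.52), arginase (PAS_chr2-2_0288, -1.51), a mitochondrial membrane protein (PAS_chr2-1_0708, -1.31), a subunit of the SAGA complex (PAS_chr1-4_0651, -1.29) and isocitrate lyase (PAS_chr1-4_0338, -1.18). Biotin synthase (PAS_chr1-3_0052) was at 0.00 in ΔROP, with the opposite sign under quantile normalization and normexp. The largest change was in the hypothetical gene PAS_chr1-4_0378, at least 112-fold higher at 24 h in GS115 and higher by 7.20 in ΔROP. Other bounds in GS115 were at least 4.11-fold higher for the methionine permease PAS_chr3_0018, at least 3.78-fold higher for the hypothetical gene PAS_chr3_0016 and at least 2.81-fold lower for the hypothetical gene PAS_chr4_0133. In ΔROP the hypothetical genes PAS_chr1-4_0377, PAS_chr1-1_0477 and PAS_chr1-3_0304 were at least 3.84-fold, 2.31-fold and 2.11-fold lower.

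The median over all genes was -0.12 in GS115 and -0.09 in ΔROP, and it was 0.04 and 0.00 when arrays were centred on their medians. Lists were therefore read against random lists. With median centring 230 genes were higher and 55 lower in GS115, and 53 and 35 in ΔROP. With normexp the counts were 164 and 54 in GS115, and 40 and 27 in ΔROP. With quantile normalization they were 92 and 55 in GS115 and 55 and 31 in ΔROP, and with cyclic loess 98 and 45, and 63 and 29.

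Ribosome biogenesis was lower at 24 h in both strains, with 71 of 81 genes below 0 and a median of -0.39 in GS115 (random range -0.29 to -0.09), and with 69 of 80 genes below 0 and a median of -0.31 in ΔROP (random range -0.20 to -0.02). Examples were an ATPase for ribosome assembly in GS115 (PAS_chr2-1_0011, -1.07) and an rRNA processing protein in ΔROP (PAS_chr3_1067, -1.07). Sugar and polyol transporters were higher in both, with medians of 0.53 (random range -0.32 to 0.33) and 0.51 (random range -0.29 to 0.27), and the hexose transporter PAS_chr1-3_0004 stood at 2.11 and 1.15. Nitrogen catabolism and permeases had medians of 0.36 in GS115 (random range -0.22 to 0.17) and 0.19 in ΔROP (random range -0.18 to 0.15), the second inside its range under quantile normalization and cyclic loess.

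In GS115 3 further lists lay below their random ranges. They were folding in the endoplasmic reticulum (-0.49, random range -0.32 to 0.25), with the DnaJ homolog PAS_chr1-3_0174 at -1.30, the proteasome (-0.27, random range -0.18 to 0.12), with 29 of 35 genes below 0, and translation factors and tRNA synthetases (-0.22, random range -0.20 to 0.05). Peroxisome biogenesis lay above (0.43, random range -0.26 to 0.30), with the AAA-peroxin PAS_chr1-4_0133 at 0.95. In ΔROP the list of glyoxylate cycle and acetate use lay below (-0.49, random range -0.30 to 0.32), with malate synthase PAS_chr4_0191 at -0.81. Regulators of carbon source use also lay below (-0.42, random range -0.38 to 0.39), with a glucose repression factor (PAS_chr4_0334) at -0.75. Other lists outside rested on saturated probes or on the scaling. In GS115 the methanol (1.15) and pentose phosphate (0.83) lists were above with saturated probes, and the biotin list (1.02) was inside under quantile normalization and cyclic loess. In ΔROP the oxidative stress list (0.36) held 5 saturated genes, heat shock proteins and chaperones (0.13) were inside under quantile normalization and cyclic loess, and cell cycle and histones (0.21) inside under cyclic loess. In all 6 lists lay above and 4 below of 26 in GS115, and 5 above and 3 below of 25 in ΔROP. Whether a list differed between the strains was described by the last comparison and not by these.

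Time differences in GS115 and ΔROP share no array, and their correlation across genes was 0.66 with a slope of 0.55. Of 4801 genes 16 were at least 2-fold higher at 24 h in both strains and 17 at least 2-fold lower, where independent lists would share about 1 each. No gene was 2-fold higher in one strain and 2-fold lower in the other.

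**Figure D4:**
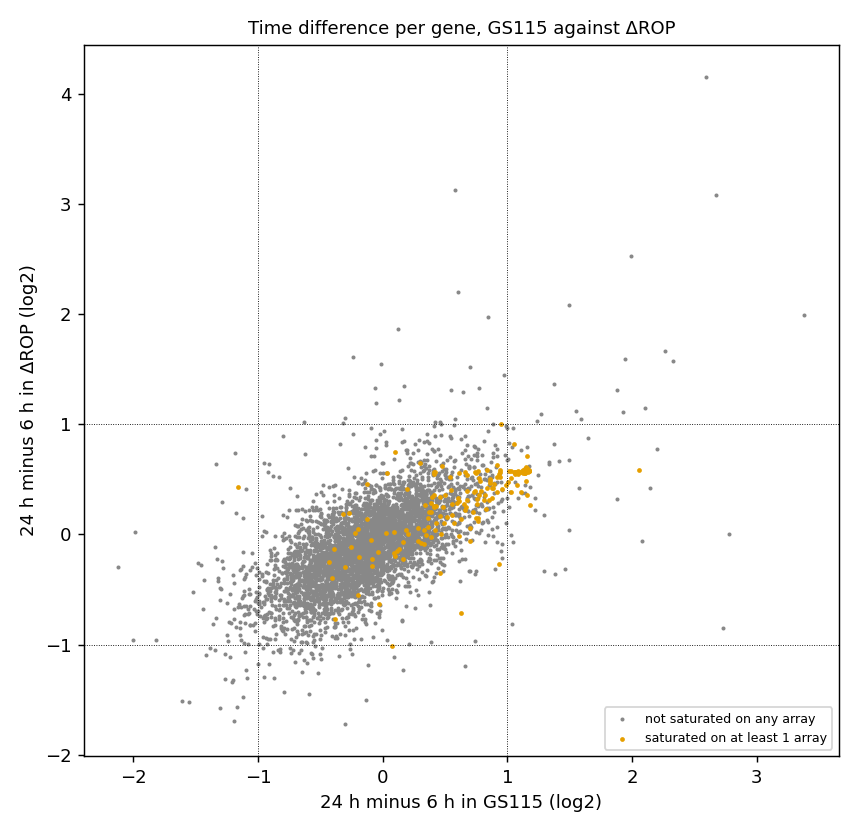
Log2 difference between 24 h and 6 h of each gene in GS115 (horizontal) and in ΔROP (vertical), with dotted lines at 2-fold. Genes saturated on at least 1 of the 4 arrays are orange, and those saturated on both arrays of a strain have a median of 1.15 in GS115 and 0.58 in ΔROP.

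The last comparison took the genotype difference at 24 h minus that at 6 h, with no residual degree of freedom and no test. It was positive by 2-fold or more for 44 of 4801 genes and negative for 40. The largest described positive values were in the ubiquitin ligase adaptor (PAS_chr2-2_0022, 1.98), a flavin monooxygenase (PAS_chr1-3_0014, 1.64), the pseudohyphal activator (PAS_chr4_0326, 1.60), a relative of monocarboxylate permeases (PAS_chr3_0278, 1.49) and the carboxylic acid permease (PAS_chr1-1_0284, 1.41). The largest negative ones included biotin synthase (PAS_chr1-3_0052, -2.78), malate synthase (PAS_chr4_0191, -1.85), the aspartic protease (PAS_chr3_0299, -1.78) and the acetate transporter (PAS_chr1-1_0418, -1.72). The proteasome list was higher, with 32 of 35 genes above 0 and a median of 0.26 (random range -0.13 to 0.11), and so were folding in the endoplasmic reticulum (0.34, random range -0.28 to 0.22) and heat shock proteins and chaperones (0.17, random range -0.16 to 0.12). The proteasome shifts at 24 h, with time in GS115 and here all use the GS115 array at 24 h. They are therefore not separate observations, and a single unusual culture on that array could give each of them. Without that array the list was inside its range, at 0.07 for the genotype at 6 h and 0.02 for time in ΔROP. Peroxisome biogenesis (-0.45, random range -0.27 to 0.19) and fatty acid beta-oxidation (-0.36, random range -0.30 to 0.14) were lower. So was the list of glyoxylate cycle and acetate use (-0.47, random range -0.41 to 0.26), which was inside its range under cyclic loess. Ergosterol synthesis was above (0.19, random range -0.21 to 0.15), and inside with saturated probes left out. Amino acid synthesis (0.16, inside under quantile normalization) and translation factors and tRNA synthetases (0.11, inside under quantile normalization, cyclic loess and normexp) were also above, and autophagy (-0.21, inside under quantile normalization and cyclic loess) below. In all 6 of 25 lists lay above and 4 below.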

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

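The tests against a mislabelled array and a later stage of the GS115 course, and the time counts that combine cyclic loess with saturated probes left out, were chosen after the result was seen. Differences between the times were not tested, since 1 array per group leaves no error for them.

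Malate synthase (PAS_chr4_0191) was higher in ΔROP by 0.59 at 6 h and was at -1.26 at 24 h. The acetate transporter (PAS_chr1-1_0418) was at 0.96 and -0.76. The ubiquitin ligase adaptor (PAS_chr2-2_0022) was at -1.04 and 0.94. The relative of monocarboxylate permeases (PAS_chr3_0278) was at -0.62 and 0.87. The pentose phosphate list had a median of 0.35 at 6 h and -0.21 at 24 h, and without saturated probes 0.07 and 0.01. They were picked out because the genotype difference went opposite ways at 6 h and 24 h, by at least 1.5-fold each for the genes and outside the random range on opposite sides for the list.

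Custom probes named ZEO, outside the gene comparisons, were well above background in ΔROP and at or near background in GS115. The log2 difference was at least 9.57 at 6 h for ZEOS1, and 10.40 at 24 h, where GS115 was just above background. For ZEOS2 it was at least 10.04 and 11.13, for ZEOAS1 at least 5.77 and 6.22, and for ZEOAS2 at least 5.23 and 6.27, at 6 h and 24 h.

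Biotin synthase, vitamin H transporter 1 and biotin:apoprotein ligase were higher in ΔROP at both times. Normalization or a trend with brightness is argued against, since the lowest of the 6 differences over 4 normalization and background alternatives was 0.94. A swap between the strains at 1 time alone is argued against by PAS_chr3_0554, at least 471-fold lower in ΔROP at each time. A swap at both times would leave the parent without this transcript and with the ZEO signal, and the deletion strain the other way round. The values argue against that only if PAS_chr3_0554 is the deleted gene. No annotation used here names it ROP, so a swap at both times is not settled by these arrays alone. A ΔROP culture at 6 h that had merely reached the stage of GS115 at 24 h is argued against. There ΔROP was above GS115 at 24 h by at least 1.05 for each gene. Stages of GS115 between 6 h and 24 h, where these genes may have peaked, and past 24 h were not measured and stay open. A lower biotin supply in the ΔROP cultures, or an effect of the deletion on these genes, may be behind the higher levels, and 1 array per group leaves both open.

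More genes differed by 2-fold between 6 h and 24 h in GS115 than in ΔROP. The ratio of counts was 2.84, and it was 1.55 at the lowest under quantile normalization and cyclic loess, just above the bound of 1.5 set for unequal brightness, so brightness is argued against as the whole cause and may be a part of it. Without saturated probes the ratio was 1.76, and with cyclic loess as well it was 1.57. The spread of the time differences over genes was less unlike than the counts. Its standard deviation was 0.50 in GS115 and 0.42 in ΔROP, and 0.44 and 0.40 under cyclic loess. The technical standard errors had a ratio of 1.01, which argues against spot noise. A single unusual culture, such as GS115 at 6 h, stays open, and so does a weaker response of ΔROP, which may be set as a hypothesis.

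Gene lists moved away from random lists in the genotype comparisons. Saturated probes are argued against as the general reason, since 11.1% of these 18 lists (2 lists, both the pentose phosphate list) returned to the random range without them. A difference in growth stage or density between the cultures was not tested and stays open beside an effect of the genotype. It may apply to any of the lists.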

How the results depend on the processing

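The combinations with saturated probes left out were chosen after the data were seen. No paired analysis was possible because each group has 1 array, so no replicates pair within a comparison, and none could be left out. The additive model compares the strains within each time. A 3-fold threshold left 4 genes higher and 4 lower in ΔROP at 6 h, 4 higher and 0 lower at 24 h, 19 higher and 6 lower with time in GS115, 14 and 3 in ΔROP, and 12 and 10 for the difference of differences; fewer genes follow from the threshold itself. No filter on dim probes gave 16 genes lower in ΔROP at 24 h against 6, and 66 against 40 lower for the difference of differences, as it counts dim genes as measured. For time in GS115, against 165 higher and 113 lower, quantile normalization gave 92 and 55, cyclic loess 98 and 45, median centring 55 lower, normexp 54 lower and saturated probes left out 59 higher. With saturated probes left out as well, quantile normalization gave 91 and 54 and cyclic loess 97 and 44. For genes lower with time in ΔROP, against 56, quantile normalization gave 31, median centring 35, cyclic loess 29 and normexp 27, and with saturated probes left out as well 30 and 27. Saturated genes account for the 59, and the cause of the other shifts was not tested. The additive model's 3 genes higher became 0 under quantile normalization, median centring, normexp, the deposited value table, no filter on dim probes and saturated probes left out, 15 under cyclic loess and 8 with a variance trend. Its 0 genes lower became 8 under cyclic loess, 1 with no filter and 3 with the trend. The cause was not tested. The other counts of 2-fold genes in the 5 comparisons stayed within 1.5 times under each alternative run for them, and the model's time counts were not recomputed. Of 67 differences of 2-fold or more among the highest and lowest genes, the pathway genes and the model's top genes, 67 kept that size and direction under quantile normalization, the value table, no filter and either rule for several probes, 66 under median centring and cyclic loess, and 60 under normexp. With saturated probes left out 65 of 65 that could be computed kept it. None of the 67 changed sign under any of these, while other differences did, such as those of pyruvate carboxylase at 6 h and acetyl-CoA carboxylase at 24 h under quantile normalization and cyclic loess, and some of bright list members with time under quantile normalization. Of 130 list medians the sign changed in 11 under quantile normalization, 14 under cyclic loess, 10 under median centring, 13 with saturated probes left out, 3 under normexp and at most 1 under the others, and no list changed from one side of its random range to the other. Signal over background limits few genes, since at least 97.4% of gene spots were well above background, while the scanner ceiling removes the brightest genes, such as those of methanol use.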

Other observations

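The tests on gene positions were chosen after the values were seen.

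Some neighbours of the vitamin H transporter gene on chromosome 1 were higher in ΔROP as well, but not each of them. At 6 h PAS_FragB_0022 was 2.30-fold higher and PAS_FragB_0025 2.20-fold higher, while PAS_FragB_0024 between the transporter and PAS_FragB_0025 had a log2 difference of -0.36. At 24 h PAS_FragB_0022, PAS_FragB_0024 and PAS_FragB_0025 were at 0.73, 0.38 and 1.39. On chromosome 2 the adjacent hypothetical genes PAS_chr2-1_0018, PAS_chr2-1_0019 and PAS_chr2-1_0020 were at 0.89, 1.58 and 1.03 at 6 h, and at 1.09, 1.41 and 0.65 at 24 h. The alcohol oxidase custom probe AOXAS was saturated on all 4 arrays, and AOXS stood at -7.84 and -7.12 in GS115 and ΔROP at 6 h, and at -5.98 and -6.51 at 24 h.

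The hypothesis was that genes with a 2-fold genotype difference lie next to each other more often than chance placement gives. At 6 h the 34 genes with a position held 3 adjacent pairs, against 0 to 1 in the middle 95% of random sets matched on level, and 2 pairs without saturated genes, against 0 to 1. At 24 h the 27 genes held 1 adjacent pair, inside the range of 0 to 1. The count at 6 h includes pairs that had been seen before it was made, so it is no independent support for the hypothesis.

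A second hypothesis was that genes changing with time lie near chromosome ends, within 50 kb of the first or last annotated gene. In GS115 17 of the 274 positioned genes did (random range 7 to 18), which decides nothing, since many of these genes were saturated and moved only with the scaling. Among those with no saturated probe 10 did (5.81%), inside the random range of 2 to 11. In ΔROP 10 of 98 did, above the random range of 1 to 8, where 3.48% of all genes lie there. Whether the strains differ in this was not tested.

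The same counts, saturated genes included, were made for every comparison. Near an end lay 6 of 34 genes of the genotype difference at 6 h (random range 0 to 4), 5 of 27 at 24 h (random range 0 to 3) and 6 of 84 of the difference of differences (random range 0 to 7). Adjacent pairs numbered 15 for time in GS115 (random range 9 to 23), 3 for time in ΔROP (random range 0 to 5) and 4 for the difference of differences (random range 0 to 4). Of the 10 counts 4 lay above their range, and counts near ends and of neighbours are not independent.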
